A study of Mus musculus with 2 samples.

How the data were processed

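H3K36me3 ChIP-seq was analysed from the forebrain of mouse embryos at 10.5 days, in 2 biological replicates that are pools of 69 and 51 embryos of both sexes, per the labels. The labels also name a possible control experiment. Both pools belong to 1 group, and no other group was analysed here.

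The deposited files were 4 peak lists in the narrowPeak format with coordinates of build mm10. Per the descriptions deposited beside them, the list of replicate 1 was derived from its own alignment and 2 further files, the list of replicate 2 from its own alignment and 1 further file, and the pooled list from both alignments. The replicated list was derived from these 3 lists, and all of its 121524 peaks were found in the pooled list. Peaks were thus called by the authors for each replicate and for the pool, so the replicates could be compared as separate lists. The peak caller, its version, its threshold and the aligner are not given in the sources used here. Each peak has a signal value that the authors' caller gave it. This signal was used only within a list, to describe peaks and to compare X with the autosomes. The deposited lists also hold the −log10 of a p-value and of a q-value for each peak as the authors' caller computed them. Where an equal number of peaks was taken from both replicates, peaks were ranked by that p-value. The smallest −log10 p in the deposited lists was 2.00 for replicate 1 and 2.02 for replicate 2. A q-value of at most 0.01, by the authors' caller, was reached by 80.1% of the peaks of replicate 1 and 83.0% of those of replicate 2. Such a permissive list holds many weak and narrow peaks, with a median width of 185 bp in replicate 1 and 202 bp in replicate 2, and a broad domain is broken into several peaks.

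Read counts are not given in the sources used here, so depth and counting error are unknown. A list called from more reads, or against another control, can hold more peaks and cover more of each gene, and the list of replicate 1 was the larger with 343015 peaks against 267274. The precision of a value is therefore shown by the SD of the 2 replicates alone.

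Peaks on the 19 autosomes and X were used, and overlapping peaks were merged. Peaks on Y and on scaffolds were left out of the comparisons. Genes, exons and introns came from the GENCODE M21 annotation of the same assembly, and no peak ran beyond the end of a chromosome. Coordinates are counted from 1. For each gene the covered share of its span was computed per replicate, and a gene of at least 1 kb was called marked at 20% or more in each replicate. Coverage along genes used 10 equal bins in genes of at least 5 kb. The share of peak sequence in annotated genes and the overlap of the replicates were set against 100 circular shifts of the peaks along each chromosome. For the classes each base was counted once, in the first class that held it. Their order was sequence within 1 kb of a protein-coding transcription start, protein-coding exons, protein-coding introns, other genes and intergenic sequence. Peaks counted as shared when they overlapped by at least 1 bp. A symbol with 2 gene identifiers was counted once.

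The gene lists covered neural progenitors, forebrain patterning, midbrain and hindbrain patterning, Hox clusters, neurogenesis and early neurons, synapses and mature neurons, astrocytes and oligodendrocytes, endothelium, erythroid cells, macrophages and microglia, mesenchyme and neural crest, and surface ectoderm. They also covered the cell cycle, splicing, ribosomal proteins, the machinery of H3K36 methylation, signalling pathways, pluripotency, other organs, imprinted genes, olfactory and vomeronasal receptors, Zfp genes, clustered protocadherins and histones. For each list the median covered share of its members was ranked among 10000 random lists of the same size from protein-coding genes, matched by decile of gene length. A list stood apart at a percentile of at most 2.5 or at least 97.5. The same ranking was applied to the mean difference between the replicates. No percentile was corrected for the number of lists ranked, so some calls may arise by chance. The median of a random list is often 0, so the test could not call a list lower there, and the mean covered share was ranked as well. Of the 22 listed imprinted genes, 19 are protein-coding and entered the test.

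The genes named in the text followed a rule. They were the 2 members with the highest and the 1 with the lowest covered share of each list (for families defined by their symbols, only the highest 2), a fixed set of forebrain, neuronal and background genes, and the 5 genes with the highest share. The rule also took the genes under the 5 longest domains, the 3 genes with the largest difference between replicates in each direction and the 3 intergenic domains with the most peak sequence. The lists, the rule, the tests, the thresholds and most alternatives were fixed before the data were examined. The tests of explanations for the X, mesenchyme and gamma protocadherin patterns were added once these patterns had been seen. The mean in place of the median, the genes without overlap, the matching of replicate differences on covered share, 6 further lists, the choice of 9 lists whose replicate difference was recomputed under the alternatives, the look-up in RefSeq, the look-up of neighbouring genes and the tests on non-coding and Y genes were chosen after seeing the data.

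The alternatives were a q-value of at most 0.01, an equal number of peaks in both replicates, peaks joined across 1 kb, either replicate left out, the replicated or the pooled list, a covered share of 10% or 40% for a marked gene, an overlap of 50%, first exons and introns left out, and random lists without matching or matched on GC content too. For the replicate differences random lists were also matched in 9 classes of covered share. The scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9 and bedtools 2.31.1. They were tested on simulated data in which peaks were planted at known shares in 200 of 16499 non-overlapping genes, with short background peaks at random over all of them. All 50 genes each with planted shares of 30%, 50% and 80% were recovered as marked, and none of the 50 with 10% or of the 16299 without a planted share. Of 200 simulated lists raised by 40 points 199 were called higher, and of 2000 random lists 62 (3.1%) were called higher and 0 lower.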

Results

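The series measured H3K36me3 in the forebrain of mouse embryos (strain label B6NCrl) at 10.5 days of development. H3K36me3 is a methylated form of histone H3 that the enzyme SETD2 places over the bodies of transcribed genes. ChIP-seq maps it by sequencing the DNA that an antibody against the modified histone pulls down. At this age the forebrain is a sheet of mostly dividing neural progenitors with the first neurons at its outer edge. The samples formed 1 group of 2 biological replicates. Each replicate was a pool of embryos of both sexes, with 69 embryos in replicate 1 and 51 in replicate 2. The group had no other tissue, stage or treatment beside it, so the comparisons were made between regions of the genome, between genes and between the 2 pools, and no p-value across samples could be had. Values with ± are the mean and the SD of the 2 replicates (n = 2). The median of a gene list was taken over the mean share of each gene, and its ± is the SD of the medians of the 2 replicates.

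The peak list of replicate 1 held 343015 peaks over 151 Mb, and that of replicate 2 held 267274 peaks over 122 Mb. The number of sequenced reads is unknown, and the number of peaks does not stand in for it. The measurement used for a gene was its covered share, which is the percentage of the gene span that lay under peaks of a replicate. A gene of at least 1 kb was called marked when its covered share was at least 20% in each replicate.

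H3K36me3 lay over the bodies of genes, in stretches that could span most of a long gene. Peaks of the authors' replicated list, joined across gaps of up to 1 kb, made 39921 domains. The longest of them ran over 134 kb of chromosome 12 (75878264 to 76012523, mm10) and covered exons and introns of Syne2, whose product ties the nucleus to the cytoskeleton. Next in length were 132 kb on chromosome 5 (101830253 to 101962051) over Wdfy3, an autophagy adaptor, and 127 kb on chromosome 11 (62312304 to 62439057) over Ncor1, a corepressor of nuclear receptors, and the adjoining Ttc19. The fourth lay over Mdn1, a ribosome assembly factor, with 121 kb on chromosome 4 (32659065 to 32780529), and the fifth over Smarcc1, a subunit of the BAF chromatin remodeller, with 111 kb on chromosome 9 (110132998 to 110243763). Covered shares of these genes were 66.0% ± 5.96 for Syne2, 63.9% ± 5.26 for Wdfy3, 70.2% ± 4.91 for Ncor1, 53.2% ± 6.41 for Ttc19, 87.6% ± 1.59 for Mdn1 and 80.2% ± 1.63 for Smarcc1. The 5613 domains of at least 10 kb held 65.2% of the peak sequence of the replicated list, while the median domain was 1620 bp long.

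Within each replicate, 95.4% ± 0.285 (SD, n = 2) of the peak sequence fell inside annotated genes, which make up 47.4% of the genome. The enrichment was 2.01-fold. Shifting the peaks along their chromosomes 100 times gave at most 50.6% for replicate 1 and 50.8% for replicate 2, so the observed shares lay above every shift. Outside the 1 kb around transcription starts, exons of protein-coding genes took 21.3% ± 1.35 of the peak sequence, 6.33-fold over their share of the genome, and introns took 72.5% ± 0.929, which was 2.00-fold. Sequence within 1 kb of a protein-coding transcription start held 0.452% ± 0.0169, a ratio of 0.282 to its share of the genome. Parts of other genes that lay outside all of these held 1.15% ± 0.128 and intergenic sequence 4.57% ± 0.277, at ratios of 0.168 and 0.0880. The SDs were far smaller than the distance of each class from its share of the genome.

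Among the domains, 430 had no annotated gene of any class within 5 kb, and they held 0.183% of the peak sequence of the replicated list. The 3 with the most peak sequence lay on chromosome 2 (84585542 to 84593653) with 51.9% ± 14.9 covered, on chromosome 5 (104580781 to 104589132) with 54.3% ± 4.86 and on chromosome 5 (30044882 to 30050443) with 62.5% ± 8.39. In the RefSeq gene table of the same assembly, looked up after these domains had been seen, they overlapped Ctnnd1, Zfp33b and Tyms. In all, 124 of the 430 domains (28.8%) overlapped a RefSeq gene.

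Of 21058 protein-coding genes, 6875 (32.6%) were marked. The highest covered shares among genes of at least 5 kb belonged to Gigyf1, a translational regulator, with 98.0% ± 0.0452, to Fam83e with 96.6% ± 2.25, to Prss53 with 96.5% ± 2.77, to the splicing factor gene Sf3b3 with 95.5% ± 0.0600 and to 1700109H08Rik with 95.5% ± 1.87. All 5 overlap another protein-coding gene, whose peaks are counted in both. The spans of Ncor1, Ttc19 and Smarcc1 above, and of Psip1, Foxg1, Tubb3, Elavl3, Eng, Cx3cr1, Alx4, Nnat and Hist1h2be below, also overlap one. At the other end, 8704 genes (41.3%) had no peak in either replicate, and 663 genes were covered to at least 80% in both. Genes of 20 to 50 kb were marked most often, 2179 of 5068 (43%). Marked genes made up 21.3% of those of 1 to 5 kb, 36.5% of those of 5 to 20 kb, 35% of those of 50 to 100 kb and 12.8% of those over 100 kb. Long non-coding genes were marked in 726 of 8893 cases (8.16%), pseudogenes in 83 of 3754 (2.21%) and genes of the remaining classes in 262 of 2563 (10.2%). The count for protein-coding genes asks for both replicates, of which replicate 1 alone gave 7773 genes and replicate 2 alone 6905. Among the 16429 genes that overlap no other protein-coding gene, a subset chosen after the data were seen, 4797 (29.2%) were marked.

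In marked genes the 3' part was covered more than the 5' part. Lhx2, a homeodomain gene needed for the cortex and the eye (chromosome 2, 38339281 to 38369733), gave an example with 50.3% ± 2.43 of its span covered. The 5' part of the gene held no peak: the peaks over it began at 38351016 in replicate 1 and at 38352626 in replicate 2 and ran past its 3' end. An annotated exon at 38350759 to 38351973 lies where the peaks begin. Spans and exons here join all annotated transcripts of a gene, and the start in use is unknown. The bare part of Lhx2 may therefore not be transcribed, which limits it as an example. In the 6157 marked genes of at least 5 kb, the share was 17.2% ± 3.24 in the first of 10 equal bins, 36.4% ± 5.17 in the bin after it, 53.0% ± 5.36 in the fifth and 67.6% ± 5.06 in the ninth. It was 66.9% ± 4.84 in the last bin, 33.5% ± 4.0 in the 5 kb downstream and 10.7% ± 1.24 in the 5 kb upstream. The last 5 bins were covered to 63.2% ± 5.23 and the first 5 to 39.7% ± 4.90, a ratio of 1.595 ± 0.0651. The 11537 genes that were not marked stayed between 1.90% and 7.42% in all bins, with the highest value in the last.

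**Figure D1:**
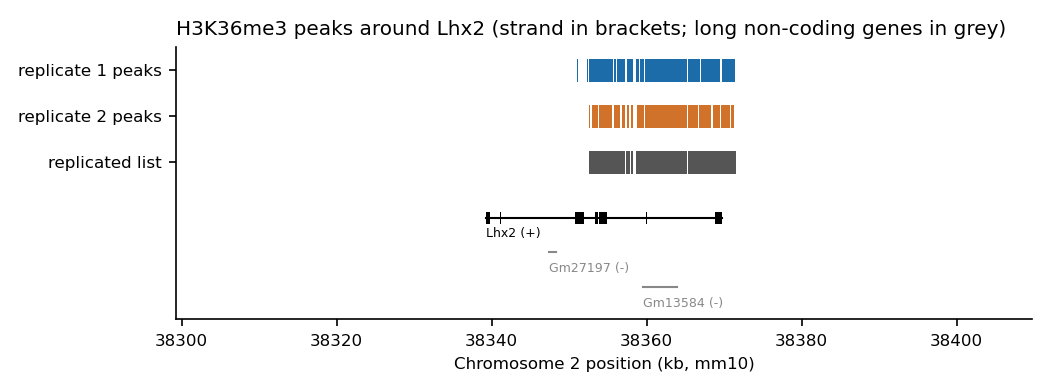
Peaks of each replicate and of the replicated list around Lhx2 on chromosome 2, from 38299281 to 38409733 (position in kb, mm10), with annotated genes, exons as boxes. Replicate 1 has 13 peaks over Lhx2, replicate 2 has 14 and the replicated list 5, all in the 3' part of the gene.

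**Figure D2:**
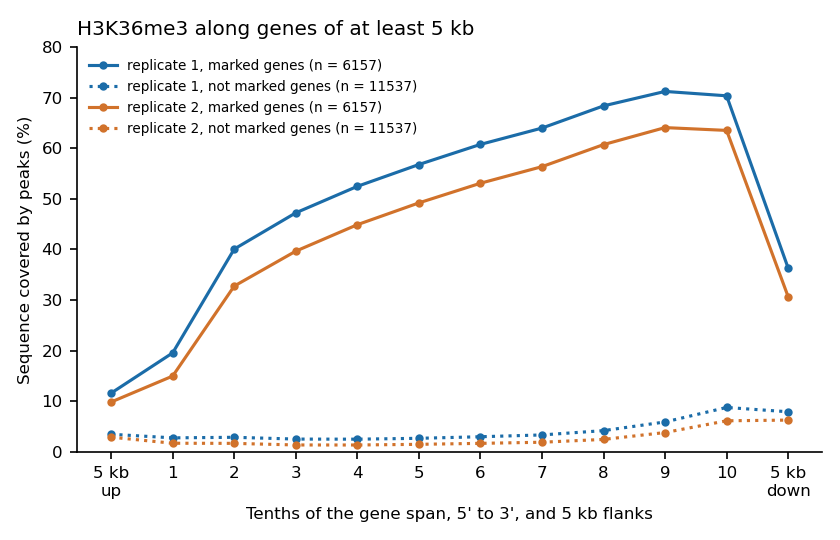
Percentage of sequence covered by peaks (vertical axis) in 10 equal bins from the 5' to the 3' end of genes of at least 5 kb and in 5 kb on either side, for 6157 marked genes (solid lines) and 11537 other genes (dotted lines) in each replicate. The mean over both replicates in marked genes is 17.2% in the first bin and 67.6% in the ninth.

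Exons of the 6875 marked genes were covered to 66.5% ± 3.57 and introns to 48.3% ± 5.35, a ratio of 1.38 ± 0.0791. The first exon stood at 14.1% ± 1.69, against 74.2% ± 3.56 for internal exons and 68.5% ± 4.12 for the last exon. It is the first of all annotated transcripts joined, and its start may not be in use in this tissue. The first intron was covered to 18.1% ± 4.40 and the other introns to 54.8% ± 5.56. The difference between the first and the later exons was more than 10 times the SD of either value. These ratios pool the sequence of many genes, which are not replicates, so no test across genes was made.

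Genes of dividing cells and of basic cell functions carried the mark. All 26 cell cycle genes of at least 1 kb were marked, with a median covered share of 83.6% ± 1.20. Among them, Mcm5 of the replicative helicase and Top2a, a topoisomerase of mitosis, reached 93.3% ± 0.251 and 93.3% ± 0.914, and the sliding clamp gene Pcna had the smallest share, 51.7% ± 0.0851. All 20 splicing genes were marked, with a median of 79.8% ± 1.12, from 95.5% ± 0.0600 for Sf3b3 and 91.9% ± 0.221 for Rbm39 down to 44.8% ± 5.38 for Ptbp2, the neural form of the polypyrimidine tract-binding protein. Of 39 genes for cytosolic ribosomal proteins 37 were marked, with a median of 65.8% ± 0.632. Rps3 had 84.0% ± 2.84 and Rpl22 79.4% ± 0.00849. Rps14 had 8.23% ± 0.749 of a span of 31.45 kb in the annotation, against a span of 5.84 kb for Rps3. The span of Rps14 overlaps another protein-coding gene. Among the writers, erasers and readers of H3K36 methylation, 19 of 22 genes were marked, with a median of 67.7% ± 5.67. Setd2 itself had 69.3% ± 4.10, the demethylase gene Kdm4a 91.1% ± 0.545, the reader gene Psip1 87.0% ± 2.59 and Phf19 2.83% ± 4.01. Each of these 4 lists lay at percentile 100 among 10000 random lists matched on gene length.

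Neural progenitor genes were marked in 18 of 24 cases, with a median of 42.4% ± 4.70 at percentile 100. Msi1, which encodes an RNA-binding protein of neural stem cells (chromosome 5, 115429599 to 115455698), was covered to 89.3% ± 1.38 and Ccnd2, a G1 cyclin gene (chromosome 6, 127125162 to 127152193), to 76.9% ± 3.87. Nes, the gene of the intermediate filament nestin (chromosome 3, 87971078 to 87980451), had 63.0% ± 10.1 and the progenitor factor gene Sox2 (chromosome 3, 34650405 to 34652461) 55.4% ± 16.6. Zic3 on the X chromosome had the smallest share of the list, 0.988% ± 1.40. Genes of the SHH, WNT, FGF and BMP pathways were marked in 19 of 32 cases, with a median of 32.6% ± 4.24 at percentile 99.9. Axin2, a target and brake of WNT signalling, had 76.4% ± 7.61 and the receptor gene Fgfr3 70.2% ± 18.2, whereas no peak lay in Fgf17, one of the FGF ligand genes.

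Forebrain patterning genes were marked in 11 of 30 cases, with a median of 16.2% ± 7.34 at percentile 94.5, so this list did not stand apart from random lists. Its mean of 20.2% ± 4.70 lay at percentile 51.2, close to the 20.1% of random lists. Nr2f1 had the highest share, 55.5% ± 13.5, followed by Otx1 with 53.5% ± 18.6. Emx2 was covered to 47.2% ± 10.7, Pax6 to 38.7% ± 11.1, Foxg1, which marks the telencephalon, to 29.5% ± 2.019 and Otx2 to 26.4% ± 3.89. The span of Foxg1 overlaps another protein-coding gene. Dlx1, a gene of ventral forebrain neurons, had no peak. Among genes that overlap no other protein-coding gene, an alternative chosen after the data were seen, the list was at percentile 98.3 with a median of 16.2%, and with random lists matched on GC content as well as length it was at percentile 73.

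Genes that pattern other parts of the body axis were bare or nearly so. None of the 39 Hox genes, which pattern the hindbrain, spinal cord and trunk, had a peak in either replicate, Hoxa1 and Hoxa10 included. None of the 18 midbrain and hindbrain genes was marked, and 14 had no peak. Tal2 had 3.11% ± 1.92, Lbx1 1.53% ± 2.17 and Atoh1 none. The medians of both lists were 0, at percentiles 45.3 and 30.3, because the medians of many random lists were 0 as well, and the preset test could not call such lists lower. The mean covered share, a measure added after the medians had been seen, was 0 for the Hox genes against 15.9% in random lists (percentile 0) and 0.267% ± 0.240 for the midbrain and hindbrain genes against 14.3% (percentile 0.03).

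Few genes of neurons and glia were marked. Of 28 genes of neurogenesis and early neurons 4 were marked, with a median of 0.249% ± 0.352 at percentile 41.6 and a mean of 7.06% ± 2.17 at percentile 1.27. Dll1, the Notch ligand gene of newborn neurons, had 58.9% ± 11.7 and Stmn1, a regulator of microtubules, 49.0% ± 2.86, and the other 2 marked genes were Tubb3 and Elavl3, named after their values were seen. Dcx of migrating neurons was covered to 0.0484% ± 0.0685 and Ebf1 had no peak. Among 22 synaptic genes 1 was marked, Dlg4 with 38.2% ± 4.74. Shank3 followed with 8.30% ± 5.31, and Gabra1 had no peak. The median of this list was 0, below the 3.29% of random lists and at percentile 0.565, and its mean of 2.49% ± 0.635 lay at percentile 0.01. The call for the synaptic median was lost without replicate 1 (percentile 3.21), with the replicated list (percentile 3.53) and without matching on gene length (percentile 9.76). Of 18 astrocyte and oligodendrocyte genes 2 were marked, Cnp with 81.2% ± 2.73 and Gja1 with 35.9% ± 0.213. The median was 0.179% ± 0.254 at percentile 13.6, the mean 8.59% ± 0.978 at percentile 0.97, and Aldh1l1 had no peak. Cnp overlaps Dnajc7, which had a share of 71.0% and was marked too.

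Markers of cells around the neural tissue were mostly bare. None of 17 endothelial genes was marked, Mmrn2 had 17.0% ± 2.99, Eng 2.53% ± 1.72, the VEGF receptor gene Kdr 1.76% ± 1.79, and Cdh5 had no peak. The median was 0 at percentile 7.54 and the mean 1.42% ± 0.479 at percentile 0.02. Among 16 erythroid genes of at least 1 kb, 1 was marked, the transferrin receptor gene Tfrc with 76.9% ± 0.622, which dividing cells of many kinds use. The X-linked Alas2, which overlaps another protein-coding gene, had 19.8% ± 9.07, and the embryonic globin gene Hbb-y and Gata1 had no peak. This list had a median of 0 at percentile 27.9 and a mean of 5.68% ± 0.805 at percentile 2.87. Of 15 macrophage and microglia genes 1 was marked, Cd68 with 98.4% ± 2.33, a gene of 1.94 kb that lies 782 bp from the marked Eif4a1. Cx3cr1, whose span overlaps another protein-coding gene, had 18.8% ± 0.419 and Adgre1 no peak. The list had a median of 0 at percentile 18.1 and a mean of 8.48% ± 0.251 at percentile 9.99.

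Among 19 mesenchyme and neural crest genes 1 was marked, the growth factor receptor gene Pdgfra with 34.7% ± 7.91. The collagen genes Col1a2 and Col1a1 had 17.2% ± 11.2 and 13.98% ± 3.96, and Dcn had no peak. The median was 1.54% ± 2.18 at percentile 46.7 and the mean 7.01% ± 2.04 at percentile 0.53. None of 12 surface ectoderm and epithelial genes was marked, with a median of 0 at percentile 9.97 and a mean of 1.08% ± 0.296 at percentile 0.17. Krt18 had 9.06% ± 4.21, Epcam 2.13% ± 0.229 and Cdh1 no peak. Pluripotency genes had no peak at all in 12 of 12 cases, Dppa3 and Dppa4 included, with the median at percentile 22.8 and the mean at percentile 0. Genes of other organs were unmarked in 19 of 19 cases, with a median of 0 at percentile 11.04 and a mean of 0.890% ± 0.327 at percentile 0. Krt10 of skin had 12.7% ± 8.46, Cpa1 of pancreas 3.42% ± 3.11 and Afp of liver and yolk sac no peak.

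Large gene families fell into covered and bare ones. Of 391 zinc finger genes named Zfp 243 were marked, with a median of 35.1% ± 5.42 at percentile 100, and Zfp869 and Zfp606 led with 96.0% ± 1.42 and 90.9% ± 0.678. None of 1029 olfactory receptor genes was marked, and 2 had a peak, Olfr543 with 11.7% ± 0.374 and Olfr1388 with 0.396% ± 0.559. None of 327 vomeronasal receptor genes had a peak, Vmn1r1 and Vmn1r10 included. Replication-dependent histone genes, most of which are shorter than 1 kb, had no peak in 66 of 67 cases, such as Hist1h1a, and Hist1h2be, which has a span of 37.5 kb in the annotation, had 0.918% ± 0.895. The medians of these 3 bare families were 0, at percentiles 50, 19.0 and 50, and their means were all at percentile 0. Without matching on gene length the medians of the olfactory and vomeronasal receptor genes lay at percentiles 0 and 0.26. Clustered protocadherin genes, which give neurons their surface identity, were marked in 21 of 57 cases, with a median of 0 at percentile 3.66 and a mean of 14.4% ± 2.52 at percentile 68.7. Pcdhgc5 and Pcdhgc4 had 47.2% ± 6.63 and 46.5% ± 7.04. Imprinted genes were marked in 9 of 19 cases, with a median of 21.1% ± 4.95 at percentile 95.3 and a mean of 28.9% ± 3.52 at percentile 96.4, so that list did not stand apart. Nnat, paternally expressed in brain, had 90.1% ± 3.33, but its span overlaps another protein-coding gene whose peaks count for both. Igf2r had 62.6% ± 7.58 and Cdkn1c no peak.

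**Figure D3:**
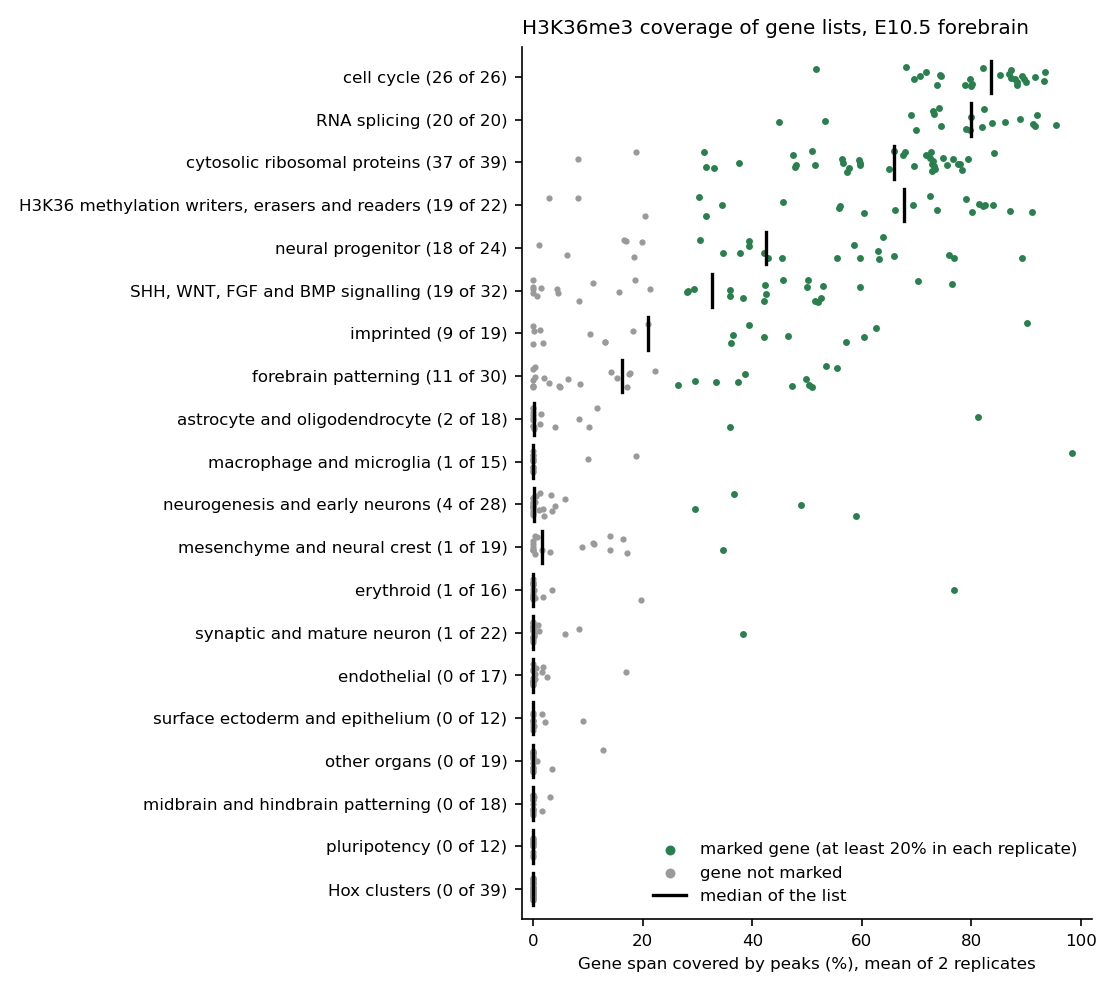
Percentage of the gene span covered by peaks (horizontal axis, mean of the 2 replicates) for each member of 20 gene lists, ordered by their mean, with marked genes in green and the list median as a bar. All 26 cell cycle genes are marked, and all 39 Hox genes are at 0.

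The replicates were compared gene by gene and peak by peak. Neural progenitor and forebrain patterning genes had the higher share in replicate 1, by more than random lists matched on length did, and mesenchyme genes in replicate 2. For forebrain patterning the call was only narrow once random lists were matched on covered share too. Emx1, a gene of the dorsal telencephalon, was covered to 65.4% in replicate 1 and 34.3% in replicate 2, Gpd1 to 62.7% and 31.2% and Wscd1 to 62.1% and 35.5%. These were the largest differences in that direction among genes of at least 5 kb. In the other direction they were Col1a2 with 9.27% and 25.1%, Alx4 of the craniofacial mesenchyme with 7.02% and 21.2% and Mdfi with 28.6% and 39.997%. Neural progenitor genes averaged 49.5% in replicate 1 and 39.0% in replicate 2, a difference of 10.5 points at percentile 100 among 10000 matched random lists, and 23 of 24 members were higher in replicate 1. Of all 21058 protein-coding genes 11441 were higher in replicate 1 and 903 in replicate 2, so counts in that direction do not by themselves set a list apart. Forebrain patterning genes differed by 6.65 points, also at percentile 100, with 23 members higher in replicate 1 and 2 in replicate 2. Zfp genes (4.82 points, percentile 100) and genes of the signalling pathways (5.52 points, percentile 99.8) shifted the same way, with 316 and 24 members higher in replicate 1 and 24 and 4 in replicate 2. Mesenchyme and neural crest genes averaged 5.57% in replicate 1 and 8.45% in replicate 2, a difference of -2.88 points against a random median of 3.07 and at percentile 0. In that list 11 members were higher in replicate 2, 2 in replicate 1 and 6 were equal. Neurogenesis and cell cycle genes differed by 3.07 and 2.09 points, at percentiles 73.6 and 12.7.

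A list without peaks differs by 0 and ranks low in this test whatever its genes encode, as the Hox genes did at percentile 0.08. A ranking among random lists matched on covered share as well as length was therefore added after the percentiles had been seen. In it the neural progenitor genes stayed at percentile 99.96 (random median 5.97 points), the forebrain patterning genes at 97.7 (4.79 points) and the mesenchyme genes at 0 (3.16 points). The forebrain percentile lay barely past the threshold. Without a correction for the number of lists ranked, that call may have arisen by chance. Zfp genes and signalling genes moved to percentiles 24.9 and 27.6, so their shift was that of other genes covered as much. Neurogenesis genes moved to 99.2 and cell cycle genes to 7.78. Surface ectoderm genes differed by -0.418 points (percentile 1.03), with 2 members higher in each replicate and 8 equal. Markers of endothelial cells differed by 0.677 points (percentile 42.6), erythroid markers by 1.14 points (percentile 66.4) and macrophage markers by 0.355 points (percentile 8.28), with the higher mean in replicate 1. With peaks joined across 1 kb the macrophage difference was -0.0898 points, higher in replicate 2. Of the other planned lists only the ribosomal protein genes were called in it, at percentile 0.06 with 1.49 points against a random median of 4.62. The percentiles describe these 2 libraries, since each side was a single pool.

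**Figure D4:**
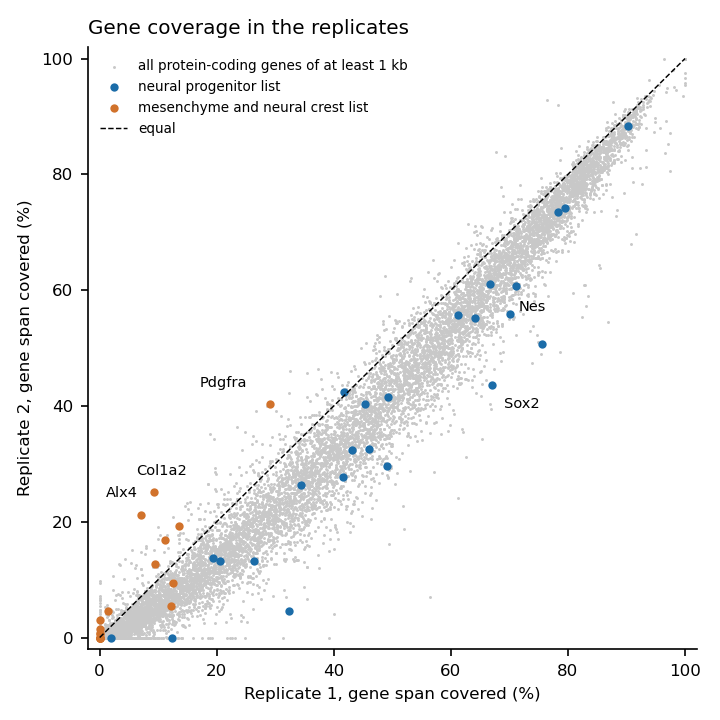
Percentage of the gene span covered by peaks in replicate 1 (horizontal axis) and replicate 2 (vertical axis) for 21058 protein-coding genes, with the neural progenitor list in blue and the mesenchyme and neural crest list in orange. Below the dashed line of equality lie 23 of 24 progenitor genes, and above it lie 11 of 19 mesenchyme genes. Of all genes 11441 lie below the line and 903 above it.

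Across all 21058 genes the covered shares of the replicates had a Pearson r of 0.989 and a Spearman rho of 0.974. Genes are not independent replicates, so these values carry no p. Replicate 1 had the higher share in 11441 genes and replicate 2 in 903. Differences over 20 points were seen in 119 genes, and in none of them was replicate 2 the higher. The merged peaks of the replicates shared 107 Mb, with a Jaccard index of 64.7%, whereas 100 shifted lists gave a mean of 2.98% and at most 4.01%. Of the peaks of replicate 1, 58.4% overlapped a peak of replicate 2 by at least 1 bp, and 86.9% of those of replicate 2 overlapped one of replicate 1. The 142539 peaks seen in replicate 1 alone had a median width of 117 bp against 324 bp for its shared peaks, and they held 13.2% of its peak sequence. The 34969 peaks of replicate 2 alone had a median width of 109 bp and held 3.52%. When 50% of both peaks had to overlap, the shared percentages were 28.8% and 37.0%.

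The authors' replicated list kept 62.2% of their pooled peaks and 91.5% of the pooled peak sequence. Pooled peaks in the list had a median signal of 3.595 and a median width of 679 bp, and those outside it 2.36 and 198 bp. Of the peaks of replicate 1, 78.4% overlapped the list, with 93.4% of the sequence, and of those of replicate 2, 95.1%, with 98.6%. Covered shares in the replicated list exceeded those of both single replicates at genes such as Sox2, with 82.4%, Nes, with 75.5%, and Pdgfra, with 61.0%.

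Genes on the X chromosome were covered less than those on any autosome. The X genes named above ranged from 0 for Gata1, 0.0484% for Dcx and 0.988% for Zic3 to 19.8% for Alas2, and Rps4x, named after its value was seen, had 57.3% ± 3.78 and was marked. Over all protein-coding genes on X, 4.13% ± 1.09 of the gene span was covered, against 12.98% ± 1.87 on the autosomes, a ratio of 0.315 ± 0.0384. The single autosomes lay between 9.57% ± 1.65 on chromosome 6 and 17.9% ± 2.26 on chromosome 11. Of 877 X genes 106 were marked (12.1%), against 6769 of 20181 autosomal genes (33.5%), with a range over the autosomes from 25.03% on chromosome 14 to 42.4% on chromosome 8. With the replicated list 20.2% of X genes and 40.4% of autosomal genes reached the threshold, and with the pooled list 23.4% and 42.3%. In each replicate the value of X lay below that of every autosome, and both pools held embryos of both sexes.

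**Figure D5:**
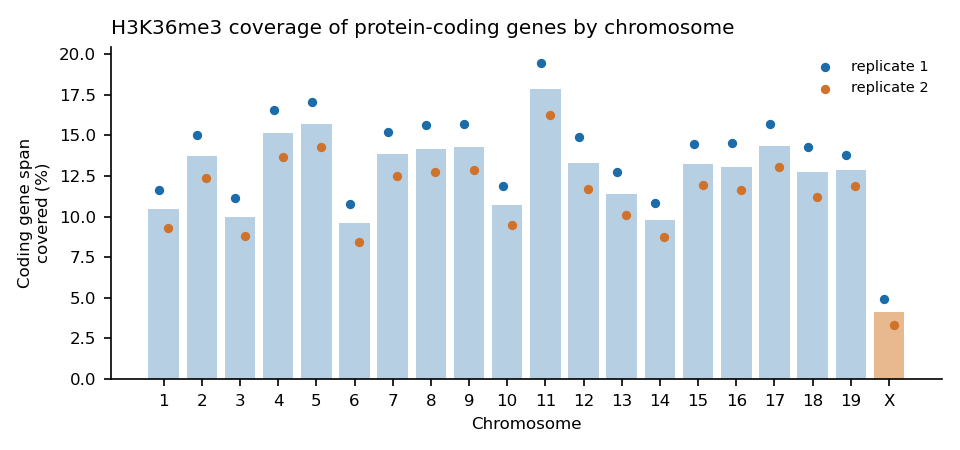
Percentage of the protein-coding gene span covered by peaks on each chromosome, with bars for the mean of the 2 replicates and points for each replicate. X stands at 4.13%, and the autosomes range from 9.57% to 17.9%.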

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

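The ranking of vessel and blood markers and the matching of the mesenchyme, progenitor and surface ectoderm lists on covered share were tests chosen only after the result was seen, as was the naming of the Y genes.

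Peaks lay on the Y chromosome and on scaffolds, which no comparison used. On Y there were 128 peaks in replicate 1, 82 in replicate 2, 111 in the pooled list and 51 in the replicated list. They centred on 4 broadly expressed genes of the short arm, named after their values were seen, which held 105 of the 128 peaks of replicate 1 (82.0%) and 52 of the 82 of replicate 2 (63.4%). Ddx3y, an RNA helicase gene, was covered to 16.1% ± 2.77 (SD, n = 2), the demethylase gene Kdm5d to 12.6% ± 5.07, the translation factor gene Eif2s3y to 4.09% ± 1.01 and Uty to 2.51% ± 1.68. The other Y genes, out of 183 protein-coding ones, had no peak in either replicate, and none of the 4 reached 20% in both. Scaffolds held 21 peaks in replicate 1, 9 in replicate 2, 17 in the pooled list and 7 in the replicated list, and 14 and 3 of those of the replicates lay on a scaffold assigned to X.

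The low coverage of X was weighed first. If X only held more genes without any mark, X genes with a pooled peak would be covered like autosomal ones, but their median share was 11.52%, below the 24.9% to 40.2% of the 19 autosomes. More genes without a mark were thus not the whole cause. They may be a part of it, since 40.7% of X genes had a pooled peak, below the 46.6% to 69.1% of the autosomes. X genes that are weakly marked on account of what they encode would also lower that median, and the test could not exclude them. The strongest peak of marked X genes had a signal of 0.7588 ± 0.0112 (SD, n = 2) times that of the median autosome, below each autosome in both replicates, as a lower signal over X genes predicts. This signal belongs to the same peaks as the covered share, so it is no independent evidence. Weaker signal over X may therefore leave fewer stretches past the threshold of the caller. Why the signal was lower stays open, since the pools mix sexes with 1 and 2 copies of X and no biological explanation was tested.

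The higher coverage of mesenchyme genes in replicate 2 was weighed next. With an equal number of peaks in both replicates the difference was -4.39 points at percentile 0.0. This setting drops the weakest peaks of replicate 1 alone, which can only lower its shares, so the sign of the difference could not have changed. A larger list in replicate 1 would raise shares there and not in replicate 2. Among random lists matched also on covered share the list was at percentile 0.0, which argued against the level of coverage as a cause. More of all non-neural cells in replicate 2 stays open. With an equal number of peaks the 11 vessel and blood markers covered to at least 1% averaged 1.13 points higher in replicate 1, at percentile 12.89 among matched lists. Of them, 6 were higher in replicate 1 and 4 in replicate 2. With all peaks they averaged 3.11 points higher in replicate 1, at percentile 28.4, with 10 higher in replicate 1 and 1 in replicate 2. Most of their shares were small, several are not specific, and the surface ectoderm list lay at percentile 1.03 with all peaks. A candidate explanation is more head mesenchyme in the pool of replicate 2, where 8 of 10 mesenchyme genes covered to at least 1% were higher, against 7.00% of all such genes, and where progenitor genes were lower by more than matched genes (percentile 99.96): Pdgfra had 29.1% and 40.3% in replicates 1 and 2, Col1a2 9.27% and 25.1% and Col1a1 11.2% and 16.8%, while Msx1 of the same list is also active in the dorsal midline of the forebrain. These values come from the same lists and libraries as the difference itself, so they are no independent evidence for that explanation. The further files behind the peaks, which differed in number between the replicates, stay open as well. The design gave no group on which a biological explanation could be tested.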

How the results depend on the processing

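The rankings by the mean, those over genes without overlap and those matched on covered share were tests chosen only after the result was seen. Of the planned recomputations of comparisons 252 stayed as reported, 21 were counted as moved, and 3 gained and 3 lost a call. Those that stayed kept their side of the threshold or lay within the spread of the replicates. For counts of marked genes the limit was 1.5 times the count reported. The Jaccard index, the percentages of shared peaks and Pearson r have no such spread. All their alternatives were counted as moved, small changes included, as were the replicated list shares at a q-value of 0.01. The replicate differences of 9 lists, chosen after seeing the data, were recomputed at a q-value of 0.01, with equal numbers of peaks and with joined peaks: 25 kept their side, 1 lost a call and 1 changed direction. Of the alternatives added later 37 stayed so and 13 gained a call, and for those 9 lists 6 kept their side, 1 gained and 2 lost a call. The marked genes ranged from 4699 at a covered share of 40% to 8734 with the pooled list, around the 6875 reported. The cause of the moves below was not tested unless the alternative itself gives it.

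At a q-value of at most 0.01 the Jaccard index of the replicates was 65.7%, the replicated list held 68.5% of pooled peaks, 85.6% of those of replicate 1 and 96.4% of those of replicate 2, and Pearson r was 0.988. With an equal number of peaks the index was 66.8%, r 0.992 and the macrophage difference at percentile 4.93. Joining peaks across 1 kb turned the macrophage difference to -0.0898 points (percentile 1.22) and gave an index of 74.9%, r of 0.977, a 3' to 5' ratio of 1.52 and an X to autosome ratio of 0.370. The X ratio was 0.357 with the replicated and 0.388 with the pooled list, and the pooled list put 94.96% of peak sequence in genes and gave a 3' to 5' ratio of 1.496. Asking for 50% of both peaks, a stricter overlap, left 28.8% and 37.0% shared, and 50% of the peak put 77.7% and 94.9% of the replicates' peaks in the replicated list. At a covered share of 40%, which favours genes covered throughout, the exon to intron ratio was 1.17 and the 3' to 5' ratio 1.48.

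The synaptic list lay at percentile 3.53 with the replicated list, at 9.755 without matching on length, and between 0.595 and 3.21 when either replicate was left out. Matching on GC content put the endothelial list at 2.295, and without matching the olfactory receptors were at 0 and the vomeronasal receptors at 0.26. Among genes without overlap forebrain patterning was at 98.25. By the mean in place of the median, 12 lists gained a call as lower, with percentiles of 0.03 for midbrain and hindbrain, 1.27 for neurogenesis, 0.97 for astrocytes and oligodendrocytes, 0.02 for endothelium, 0.53 for mesenchyme, 0.17 for surface ectoderm and 0 for Hox, pluripotency, other organs, olfactory and vomeronasal receptors and histones. The synaptic list kept its call at 0.01, and the protocadherins, without a call, went from 3.66 to 68.7. Matched on covered share, the replicate difference lay at 99.16 for neurogenesis, 42.62 for endothelium and 8.28 for macrophages.

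Of the 95 genes named by the rule, none lost a share of 20% under any alternative list of peaks, and 2 without replicate 1, 1 without replicate 2, 8 with joined peaks, 8 with the replicated list and 9 with the pooled list passed it. A marked gene could not lose that share when a replicate was left out or peaks were joined. Of all recomputed values of the named genes 470 were counted as the same and 195 as moved. No paired analysis was possible because the design has a single group. Depth is unknown, so a gene without a peak may carry H3K36me3 below the threshold, and 41.3% of protein-coding genes had no peak in either replicate. Joining peaks raised the marked genes from 6875 to 8010, but it only fills gaps between peaks and does not bear on genes without any.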

Other observations

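The tests on 6 further gene lists and on long non-coding genes were chosen only after the result was seen, and so were the genes named from them.

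Genes behind growth disorders of the brain and behind chromatin structure were covered in most cases. Of 20 primary microcephaly genes 18 were marked, with a median covered share of 66.5% ± 2.34 (SD, n = 2) at percentile 100 among 10000 random lists matched on gene length. Aspm, a spindle pole gene of neural progenitors, had 85.2% ± 3.80, Cep152 of the centriole 80.7% ± 3.28 and Cdk6 1.31% ± 0.970. Among 19 genes of chromatin remodelling and cohesin 16 were marked (median 73.0% ± 5.46, percentile 100), with 92.4% ± 0.642 for Chd4 and 81.9% ± 2.83 for Smarca4, the ATPase of the BAF complex. Polycomb genes were marked in 13 of 20 cases (median 43.6% ± 3.603, percentile 99.4), with 67.1% ± 2.38 for the methyltransferase gene Ezh2 and 10.1% ± 3.97 for its paralogue Ezh1. Genes of oxidative phosphorylation were marked in 24 of 26 cases (median 65.9% ± 3.69, percentile 100). Genes of intraflagellar transport and the cilium were marked in 13 of 20 cases, with a median of 30.4% ± 8.31 at percentile 96.8 that did not stand apart. Like most protein-coding genes (11441 higher in replicate 1 and 903 in replicate 2), all 20 of these genes and all 20 microcephaly genes were covered more in replicate 1, by 9.39 and 6.75 points (percentiles 100 and 99.8). Among random lists matched on covered share too, they lay at percentiles 97.6 and 93.4, and the Polycomb genes, with 3.20 points, at 1.08. Axon guidance genes were marked in 4 of 24 cases, with a median of 0.756% ± 0.310 at percentile 42.4, where Plxna1 had 80.8% ± 2.25 and Dcc 0.0304% ± 0.0430.

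Long non-coding genes away from protein-coding genes were rarely marked, 85 of 5110 (1.66%), against 641 of the 3783 that overlap a protein-coding gene (16.9%). The maternally expressed Meg3 on chromosome 12 (109541001 to 109571726) was covered to 70.7% ± 5.35 and Mirg, further along the same imprinted cluster, to 84.6% ± 0.262. Malat1, an abundant nuclear RNA, had 71.7% ± 7.64, whereas its neighbour Neat1 had 0.395% ± 0.0477. Mir9-3hg, a host of the neural microRNA miR-9, had 61.4% ± 13.7, Miat 47.7% ± 2.021 and Rmst 30.2% ± 15.0. Of the X inactivation centre, Ftx had 44.2% ± 5.95 and Xist 9.59% in replicate 1 and 0.419% in replicate 2. The imprinted Kcnq1ot1 had 33.8% ± 2.56 and H19 no peak. The genes from Neat1 on were picked by name, whether or not they overlap a protein-coding gene, whose peaks would count for both.

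Some marked genes of lists for other cell types had a marked gene nearest to them. The 5 kb upstream of Cd68 were covered to 86.2% ± 0.594 and the 5 kb downstream to 29.4% ± 3.34. The 5 kb downstream of Cnp were covered to 97.8% ± 1.17 and the 5 kb upstream of Dlg4, next to the marked Acadvl, to 41.9% ± 0.580, with no peak in the 5 kb on the other side of either gene. Tfrc, whose nearest gene was the marked Tnk2 at 11079 bp, had no peak in the 5 kb upstream and 12.1% ± 0.0990 downstream. The nearest protein-coding genes of Pdgfra and Gja1, 74398 and 148640 bp away, were not marked. Pdgfra had no peak upstream and 5.06% ± 4.33 downstream, and Gja1 had none on either side.

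The 21 marked protocadherin genes were all of the gamma cluster on chromosome 18, while none of the 14 alpha and 22 beta genes had a peak. The gamma genes share their 3' constant exons, so their spans overlap and peaks over the shared 3' part count for each of them. Against these exons as the whole cause, exon sequence that belongs to a single gamma gene had a median covered share of 55.87%, beside 54.6% for shared exons, and 19 of 21 genes reached 20% in their own exons. The exceptions were Pcdhga1 with 0% and Pcdhga2 with 12.4%. Transcripts that start at an upstream gamma exon run through the ones downstream, so the promoters in use stay open, and no biological explanation was tested.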
